A study of Mus musculus with 6 samples.

How the data were processed

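RNA was measured in 6 libraries of sorted mouse lung ILC2s, 3 from WT and 3 from ICOS KO mice. Per the labels' protocols, RNA of the cultured cells was turned into cDNA with a SMARTer low-input kit, which amplifies full-length cDNA by PCR and has no molecular identifiers in the sources used here. The design text speaks of duplicates, while 3 libraries per genotype were present, and all 6 were used. Per the submitters' processing notes, the tools were Partek 10.0, STAR 2.7.8 and DESeq2 and the genome build was mm10; the annotation, the counting method and its strand setting are not given in the sources used here.

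The authors deposited 1 table of estimated counts per gene, with a line per library and a column per gene. Of its values 39.4% were not whole, none was below 0, and the lowest total of a gene over the 6 libraries was 10. Libraries were matched to groups by the library name in the labels, and the genotype column of the table gave the same groups. The estimated counts were rounded to whole numbers before testing. Estimated counts can divide reads between copies, so values of near-identical genes (immunoglobulin segments, tryptases, MHC genes, chemokines) and of overlapping genes are uncertain. Library totals ranged from 13738062 to 18736474, and a floor of 3 reads was 0.0562 CPM over the WT group and 0.071 CPM over the ICOS KO group. Without molecular identifiers reads are not independent molecules.

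Genes were kept with edgeR's filterByExpr, which left 13691. Counts were normalised with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3), ICOS KO against WT without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 18.5%. SE values are those of the log2 fold change implied by the F statistic, and CPM are TMM-normalised. Pairs of libraries were compared by correlation across genes (Pearson r of log2 CPM from 0.948 to 0.979, prior count 2) and by a chi-square of their counts, which was at least 8.91 per degree of freedom in every pair, so no library was a second copy of another. Gene lists were written before the data were examined: 20 pathway lists and lists of other cell types, quality genes and the region of Icos. The pathway lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry, with adjustment over the 20 lists. An exact permutation test over the splits of 6 libraries was added for Icos and Il10.

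The rule for named genes was also fixed before the data were examined. It took Icos and the 10 largest rises and 10 largest falls among called genes. These had separated libraries and a mean of at least 5 CPM in the higher group, and predicted models and pseudogenes were left out. It also took up to 4 members with the smallest p in each pathway list. A further 18 genes were fixed by name, among them Il10, Cd28, Ctla4 and Acads. For the other lists it took called members or the 3 most abundant. This gave 163 genes; the text describes most called ones with their values and summarises the rest as counts, and the alternatives were run on all of them but 3, whose results are not reported here. A further 12 genes (Glo1, Btbd9, Dnah8, 1700097N02Rik, Fcmr, Il24, Irf4, Il10ra, Il4, Ccl4, Tnfrsf9 and Vsir) were chosen after their values were seen. Irf7, Cd6, Cd79a, Gata2, Kit, Tph1, Hpgds, Prg2, Epx, Elane, Malat1 and CT010467.1 were likewise named after their values were seen, and the alternatives were not run on them. Positions come from GENCODE M21 (GRCm38, the build mm10 names) by symbol for 17691 genes and from RefSeq for 353, and 78 symbols had no match.

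The alternatives were DESeq2 median-of-ratios (RLE), upper-quartile and total-count scaling; DESeq2 1.42.0, limma voom and voom with quality weights; no filter and a filter of at least 5 CPM in 3 libraries; the replicate number as a block; each library left out in turn; mitochondrial and haemoglobin genes left out; and a 2-fold minimum. A correction for transcript length and GC content (known for 99.2% of tested genes) and a fit without marker and antigen receptor genes were added after the data were seen. The fit was tested on simulated counts for ICOS KO against WT over 13444 genes, with 200 genes changed and a list of 25 others raised by 0.4 on the log2 scale. It recovered 44% of 50 genes at 1.5-fold, 56% of 50 at 2-fold, 78% of 50 at 4-fold and 94% of 50 at 8-fold, and of its 152 calls 4 were in the raised list and 12 were unchanged genes; with no gene changed it called 4.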

Results

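Messenger RNA was measured in group 2 innate lymphoid cells (ILC2s), lymphocytes that lack antigen receptors and release type 2 cytokines, which had been sorted from mouse lung and then cultured. The series holds 3 libraries from wild-type (WT) mice, whose genotype the labels give as BALB/C BYJ, and 3 from mice with a targeted allele of Icos, the gene of the inducible co-stimulator receptor (ICOS KO). The labels give C.129S4-Icostm1Shr/J for these mice, a strain name that includes that of the allele. WT and ICOS KO thus differ in strain name as well as in Icos. A difference given below can stem from strain DNA or from the loss of Icos, and the design cannot tell these apart. The WT libraries held 18517247, 18736474 and 14976130 estimated counts. The ICOS KO libraries held 15543034, 13950621 and 13738062. A floor of 3 reads corresponded to 0.157 to 0.225 CPM (counts scaled to library size) in a single library, and such floors cover counting error only. The labels do not say whether the libraries of a genotype came from separate mice or cultures, so p-values measure the spread between these libraries, which may be technical. The genotypes separated along the first principal component, which held 40.4% of the variance. Within each genotype, libraries ranked on it as they did on mitochondrial share and on the nuclear RNA Malat1, both given below. The component may therefore not reflect genotype alone. ICOS KO replicate 2 stood farthest from the others, with a score of 54.71 against 9.33 and 27.51 for the other ICOS KO libraries and -35.02 to -22.28 for the WT libraries.

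Icos, on chromosome 1 at 60977927 to 61000320 (GRCm38), was lower in every ICOS KO library. It stood at 434, 462 and 502 CPM in WT and at 140, 170 and 161 CPM in ICOS KO. The group means were 466 ± 33.9 and 157 ± 15.6 CPM (SD, n = 3 each), a log2 fold change of -1.57 ± 0.10 (SE; edgeR adjusted p = 1.27e-05). An exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 libraries allow. The gene overlaps the predicted gene Gm37039, and counts for the whole gene do not show which exons the remaining reads came from.

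**Figure D1:**
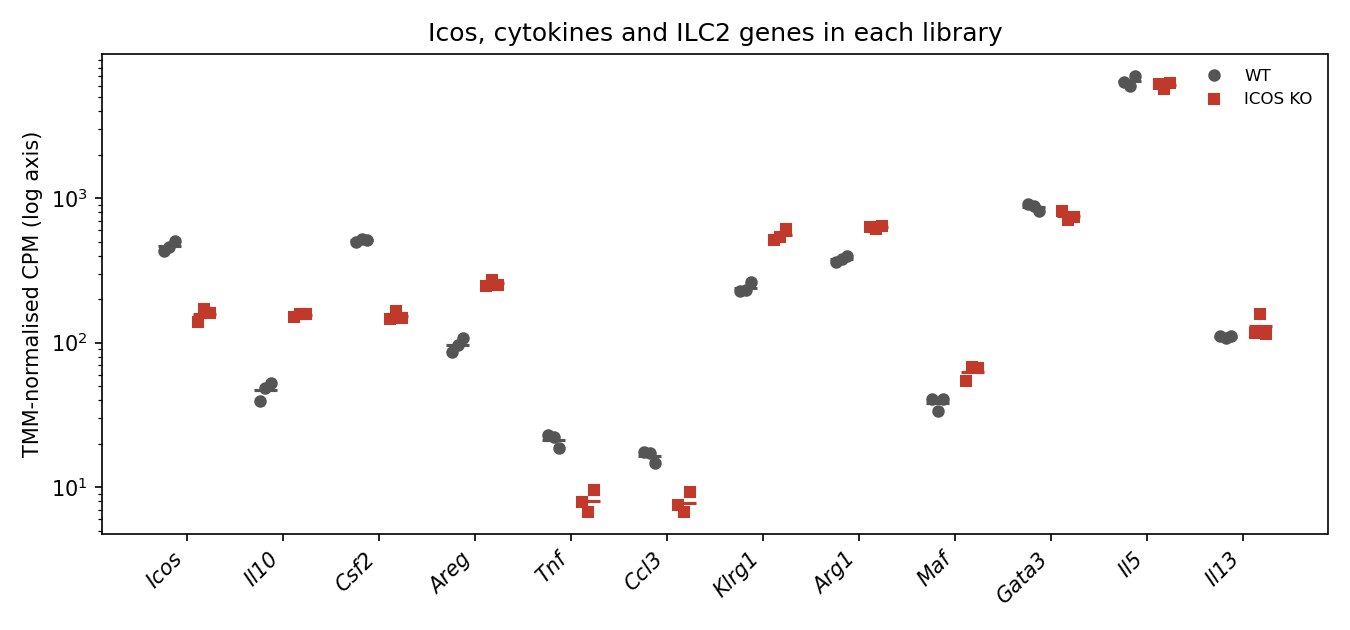
TMM-normalised CPM (log axis) of 12 genes in the 3 WT libraries (grey circles) and the 3 ICOS KO libraries (red squares), with the group mean as a line. Icos and Csf2 sat lower, and Il10, Areg and Klrg1 higher, in all 3 ICOS KO libraries than in any WT library.

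The first comparison asked which transcripts differed between ICOS KO and WT ILC2s. The rises of known genes were led by immunoglobulin segments, Macroh2a1, Otud3, Lyplal1 and Acads. The falls were led by the immunoglobulin gene Ighg2b, followed by mast cell and basophil proteases, Dnah17, Cmpk2, Scin and Rtp4. Macroh2a1, the histone variant macroH2A1 (chromosome 13, 56073622 to 56135626), rose from 38.1 ± 1.31 to 399 ± 15.0 CPM (SD, n = 3 each; 10.5-fold). Acads, the short-chain acyl-CoA dehydrogenase of mitochondrial fatty acid oxidation (chromosome 5, 115110299 to 115119346), rose from 24.9 ± 3.84 to 93.8 ± 5.32 CPM. Strain and genotype go together here, so this rise cannot be told apart from a strain difference. Otud3, a deubiquitinase, rose from 0.551 ± 0.250 to 5.86 ± 0.936 CPM, and Lyplal1, a lysophospholipase-like protein, from 1.02 ± 0.314 to 8.18 ± 1.11 CPM. Dnah17, a dynein heavy chain of motile cilia, fell from 23.1 ± 1.69 to 1.44 ± 1.55 CPM, though it overlaps Pgs1. Its fall of 16.2-fold was 41.2-fold without ICOS KO replicate 2, which stood at 3.23 CPM against 0.646 and 0.445 in replicates 1 and 3. Scin, the actin-severing protein scinderin, fell from 13.6 ± 3.16 to 2.01 ± 0.887 CPM. Igkv3-2 had no read in WT and was at least 106-fold higher in ICOS KO. Ighg2b had no read in ICOS KO and was at least 205-fold lower there, both against a floor of 3 reads over the group. The first bound rests on ICOS KO replicate 1 (15.6 CPM against 0.902 and 1.41 in replicates 2 and 3) and was 20.6-fold without it, 68.3-fold without WT replicate 1 and 68.4-fold without WT replicate 2. Ighg2b stood at 25.3, 16.3 and 2.10 CPM in WT, and its bound was 130-fold without WT replicate 1 or ICOS KO replicate 1. The other segments among the 10 largest rises were Igkv1-135, Igkv9-129, Ighv12-3, Iglc3 and Igkv4-91, and reads of such segments can be shared between near-identical copies. The calls of Igkv3-2 (without any of the WT replicates), Igkv9-129 (without WT replicate 2 or 3 or ICOS KO replicate 2 or 3) and Ighv12-3 (without WT replicate 3 or ICOS KO replicate 2 or 3) were lost, with adjusted p up to 0.121. DESeq2 called neither Igkv9-129 (adjusted p = 0.268) nor Ighv12-3 (0.148, and 0.0504 in edgeR with the length and GC trend removed), and voom did not call Ighg2b (0.0711).

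Of 13691 genes tested, 451 passed an edgeR adjusted p of 0.05, of which 176 were higher and 275 lower in ICOS KO, and 201 of them changed at least 2-fold (61 higher, 140 lower). All 451 had every ICOS KO library on the same side of every WT library, as had 24.4% of tested genes, where chance gives 10%. The higher genes made up 39% of calls, 28.2% with library totals alone as the scaling and 58% once each library's trend with transcript length and GC content was removed. The count was 193, 194 and 369 without WT replicate 1, 2 and 3, and 1090, 312 and 216 without ICOS KO replicate 1, 2 and 3. DESeq2 called 909 genes and voom with sample quality weights 906.

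Il10, the gene of the anti-inflammatory cytokine interleukin-10 (chromosome 1, 131019845 to 131024974), rose in ICOS KO, and the study's title names interleukin-10 production as its subject. It stood at 39.5, 49.0 and 52.5 CPM in WT and at 150, 159 and 158 CPM in ICOS KO, means of 47.0 ± 6.74 and 155 ± 5.09 CPM (SD, n = 3 each) and a log2 fold change of 1.73 ± 0.12 (SE; edgeR adjusted p = 1.36e-05). Its exact permutation p was 0.1, the smallest possible. Of 19 tested genes of the IL-10 programme list, 4 rose and 4 fell, or 7 and 4 when adjusted over the list alone. Gzmb, the protease granzyme B, rose from 205 ± 24.8 to 393 ± 96.7 CPM, and Maf, a transcription factor that drives Il10, from 38.35 ± 4.203 to 62.79 ± 7.199 CPM. Bhlhe40, a repressor of Il10, fell from 117 ± 19.95 to 58.4 ± 3.24 CPM, and Id3, an inhibitor of E proteins, from 43.2 ± 6.77 to 19.4 ± 4.28 CPM. Irf4, a transcription factor that supports Il10 in T cells, also fell, from 80.4 ± 6.69 to 49.3 ± 6.50 CPM. So did Il10ra, a chain of the interleukin-10 receptor, from 123 ± 11.0 to 83.3 ± 7.13 CPM. The fourth rise was that of Tigit, given below. Prdm1, which encodes Blimp-1, stood at 45.5 ± 1.43 and 51.0 ± 4.24 CPM (edgeR adjusted p = 0.456). The call of Gzmb was lost without WT replicate 2 (adjusted p = 0.0564), and those of Maf, Irf4, Il10ra and Tigit without WT replicate 1 or 2 or ICOS KO replicate 3 (adjusted p up to 0.128).

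Other cytokines moved in both directions. Of 17 tested type 2 and growth factor cytokine genes, 2 rose and 4 fell, or 3 and 4 when adjusted over the list alone. Csf2, which encodes GM-CSF (chromosome 11, 54247271 to 54249667), fell from 512 ± 11.5 to 153 ± 11.3 CPM (SD, n = 3 each), a log2 fold change of -1.74 ± 0.09 (edgeR adjusted p = 3.57e-06). Areg, which encodes the epithelial repair factor amphiregulin (chromosome 5, 91139599 to 91148432), rose from 96.7 ± 10.6 to 257 ± 14.8 CPM (1.41 ± 0.11; edgeR adjusted p = 2.72e-05). Il4, which encodes interleukin-4, rose from 17.4 ± 1.93 to 29.6 ± 4.09 CPM (edgeR adjusted p = 0.0217). Tnf fell from 21.3 ± 2.19 to 8.05 ± 1.41 CPM, and the chemokine gene Ccl3 from 16.5 ± 1.43 to 7.80 ± 1.28 CPM, a call lost without WT replicate 1 or 2 (adjusted p up to 0.0618). Ccl4 fell from 13.6 ± 1.83 to 6.54 ± 1.87 CPM, a call lost without any of the WT replicates or ICOS KO replicate 2 (adjusted p up to 0.186). Reads of Ccl3 and Ccl4 may be shared with their near copies. The call of Il4 was lost without WT replicate 1 or 2 or ICOS KO replicate 2 or 3 (adjusted p up to 0.131). It was also lost with the length and GC trend removed (0.181), where the log2 fold change went from 0.77 to 0.35. Il5 and Il13, also typical of ILC2s, were not called: Il5 stood at 6460 ± 533 and 6049 ± 309 CPM (edgeR adjusted p = 0.504), and Il13 at 110 ± 2.41 and 130 ± 24.5 CPM (edgeR adjusted p = 0.313). Mast cell and basophil markers, described further on, fell with Csf2 and Tnf.

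Of 27 tested ILC2 identity genes, 4 rose and 1 fell, or 6 and 3 when adjusted over the list alone. Klrg1, a receptor of mature ILC2s (chromosome 6, 122270596 to 122282882), rose from 240 ± 19.4 to 557 ± 49.4 CPM (SD, n = 3 each; edgeR adjusted p = 5.9e-05). Arg1, which encodes arginase 1, rose from 380 ± 17.8 to 628 ± 14.4 CPM, and Cysltr1, a leukotriene receptor, from 185 ± 19.3 to 293 ± 6.29 CPM. Rora, a transcription factor that ILC2s need, fell from 211 ± 7.75 to 152 ± 5.997 CPM. Il1rl1, the receptor of interleukin-33, rose from 378 ± 8.72 to 514 ± 78.3 CPM at an edgeR adjusted p of 0.0495. Gata3 (868 ± 51.0 and 753 ± 53.1 CPM; edgeR adjusted p = 0.227) and Il7r (71.5 ± 8.50 and 79.8 ± 3.85 CPM; edgeR adjusted p = 0.47) were not called. The call of Il1rl1 was lost without any of the WT replicates or ICOS KO replicate 3, and that of Rora without WT replicate 1 or 2 or ICOS KO replicate 3 (adjusted p up to 0.214 and 0.104). With library totals alone as the scaling, the adjusted p of Il1rl1 was 0.101, and with no filter on low counts 0.0625.

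Of 21 tested co-stimulatory and checkpoint receptor genes, 4 rose and 2 fell, or 6 and 3 when adjusted over the list alone. Tnfsf4, which encodes OX40 ligand, fell from 32.4 ± 2.66 to 10.0 ± 2.82 CPM (SD, n = 3 each; edgeR adjusted p = 0.000889), and Cd96 fell from 11.7 ± 2.13 to 5.12 ± 0.218 CPM. Tnfrsf18, which encodes GITR, rose from 652 ± 16.8 to 1093 ± 123 CPM, and Tigit from 16.4 ± 2.48 to 29.6 ± 4.86 CPM. Tnfrsf9, which encodes 4-1BB, rose from 477 ± 36.5 to 623 ± 22.6 CPM and Vsir, which encodes VISTA, from 10.9 ± 1.85 to 21.1 ± 6.16 CPM. Cd28 (8.76 ± 1.22 and 6.80 ± 1.55 CPM; edgeR adjusted p = 0.423) and Ctla4 (11.1 ± 1.10 and 17.1 ± 1.40 CPM; edgeR adjusted p = 0.0748), whose genes neighbour Icos, were not called. Of 18 genes of the cytokine receptor and STAT target list, 3 rose and 2 fell (4 and 4 when adjusted over the list alone). Socs3, a feedback inhibitor of cytokine signalling, rose from 251 ± 22.2 to 387 ± 42.9 CPM, and Stat6, the transcription factor of interleukin-4 signalling, fell from 210 ± 25.0 to 133 ± 30.6 CPM. The kinase gene Pim2 rose from 179 ± 12.2 to 246 ± 10.9 CPM and Osm, which encodes oncostatin M, from 128 ± 3.56 to 179 ± 23.1 CPM. Of 25 genes of the PI3K, AKT and mTOR list, Pik3ap1, an adaptor of PI3K, rose from 27.4 ± 5.20 to 56.6 ± 6.46 CPM and no other was called, over all genes or adjusted over the list alone. The calls of Cd96, Tigit, Socs3 and Stat6 were each lost without WT replicate 1 or ICOS KO replicate 3, those of Tigit and Stat6 also without WT replicate 2, that of Cd96 also without WT replicate 3 and that of Stat6 also without ICOS KO replicate 2 (adjusted p up to 0.197). Those of Tnfrsf9, Vsir and Osm were lost in 5 of the 6 fits that left out a library (adjusted p up to 0.206). The fit that kept the call was that without ICOS KO replicate 3 for Vsir and ICOS KO replicate 1 for the others. The call of Pim2 was lost without any of the WT replicates or ICOS KO replicate 3 (up to 0.12). With no filter on low counts the calls of Stat6 and Vsir were lost (up to 0.0587), with library totals alone those of Tnfrsf9, Vsir, Pim2 and Osm (up to 0.09). The call of Vsir was also lost with voom (0.0623, and 0.0688 with quality weights).

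The study's title also names cholesterol and cortisol biosynthesis. The 22 tested cholesterol biosynthesis genes had a median log2 fold change of 0.20, with 15 positive and 7 negative, and camera placed the list higher in ICOS KO (adjusted p = 0.0216 over 20 lists; adjusted p = 0.96 with an estimated correlation). In this list 2 genes rose, over all genes and when adjusted over the list alone. Fdps, which encodes farnesyl diphosphate synthase, rose from 276 ± 14.7 to 440 ± 54.3 CPM (SD, n = 3 each; log2 fold change 0.68 ± 0.10, edgeR adjusted p = 0.00419). Pmvk, phosphomevalonate kinase, rose from 56.0 ± 1.32 to 78.2 ± 7.95 CPM (edgeR adjusted p = 0.041). Sqle, squalene epoxidase, stood at 137 ± 24.6 and 128 ± 19.7 CPM (edgeR adjusted p = 0.745). Hmgcs1 had a log2 fold change of 0.21 ± 0.14 (edgeR adjusted p = 0.412). The camera call was lost without WT replicate 3 (adjusted p = 0.228), ICOS KO replicate 1 (0.263) or ICOS KO replicate 3 (0.186), and the call of Pmvk in 5 of the 6 fits that left out a library, all but that without ICOS KO replicate 1 (adjusted p up to 0.188). The adjusted p of Pmvk was also 0.0778 with the length and GC trend removed, 0.055 with no filter on low counts and 0.0641 with library totals alone.

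Of 16 tested cholesterol sensing and uptake genes, Lipa, the lysosomal acid lipase, fell from 92.1 ± 3.61 to 49.3 ± 5.31 CPM (SD, n = 3 each; edgeR adjusted p = 0.0012) and none rose in edgeR, or 1 rose and 1 fell when adjusted over the list alone, while DESeq2 called 2, voom 1 and weighted voom 2. Npc2, a lysosomal cholesterol carrier, stood at 128 ± 12.1 and 169 ± 14.1 CPM (edgeR adjusted p = 0.0728). It was called higher under 5 of 18 alternatives, with an adjusted p of at least 0.0156. These were DESeq2, weighted voom, the replicate number as a block, the length and GC trend removed, and the fit without ICOS KO replicate 1. The list's median log2 fold change was 0.02 and the mean -0.04, with camera's direction up. Srebf2, the sterol-sensing transcription factor, stood at 202 ± 25.7 and 231 ± 2.996 CPM (edgeR adjusted p = 0.334). None of 13 cholesterol efflux and esterification genes was called by edgeR, over all genes or adjusted over the list alone, nor by DESeq2 or by voom with or without quality weights, and 2 had an unadjusted p under 0.05. The steroid hormone biosynthesis list was not past the threshold (camera adjusted p = 0.831, direction up, with a median log2 fold change of -0.01 over 15 genes). In it Cyp11a1, the enzyme that turns cholesterol into pregnenolone, rose from 2116 ± 101 to 2610 ± 85.8 CPM, a log2 fold change of 0.30 ± 0.07 (edgeR adjusted p = 0.0461), and 2 genes rose when adjusted over the list alone. That call, of a gene that overlaps the predicted gene Gm17322, was lost without any of the WT replicates or ICOS KO replicate 3 (adjusted p up to 0.214), with library totals alone as the scaling (0.124) and with no filter on low counts (0.059). Of 18 genes of the glucocorticoid receptor and target list, Errfi1, an inhibitor of EGF receptor signalling, rose from 9.71 ± 1.99 to 19.5 ± 1.003 CPM and Anxa1, annexin A1, fell from 117 ± 13.4 to 70.9 ± 6.20 CPM, with 1 and 1 also when adjusted over the list alone. The call of Errfi1 was lost without WT replicate 2 or ICOS KO replicate 3 (adjusted p up to 0.075). Nr3c1, the glucocorticoid receptor, stood at 199 ± 8.51 and 210 ± 4.64 CPM (edgeR adjusted p = 0.667).

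**Figure D2:**
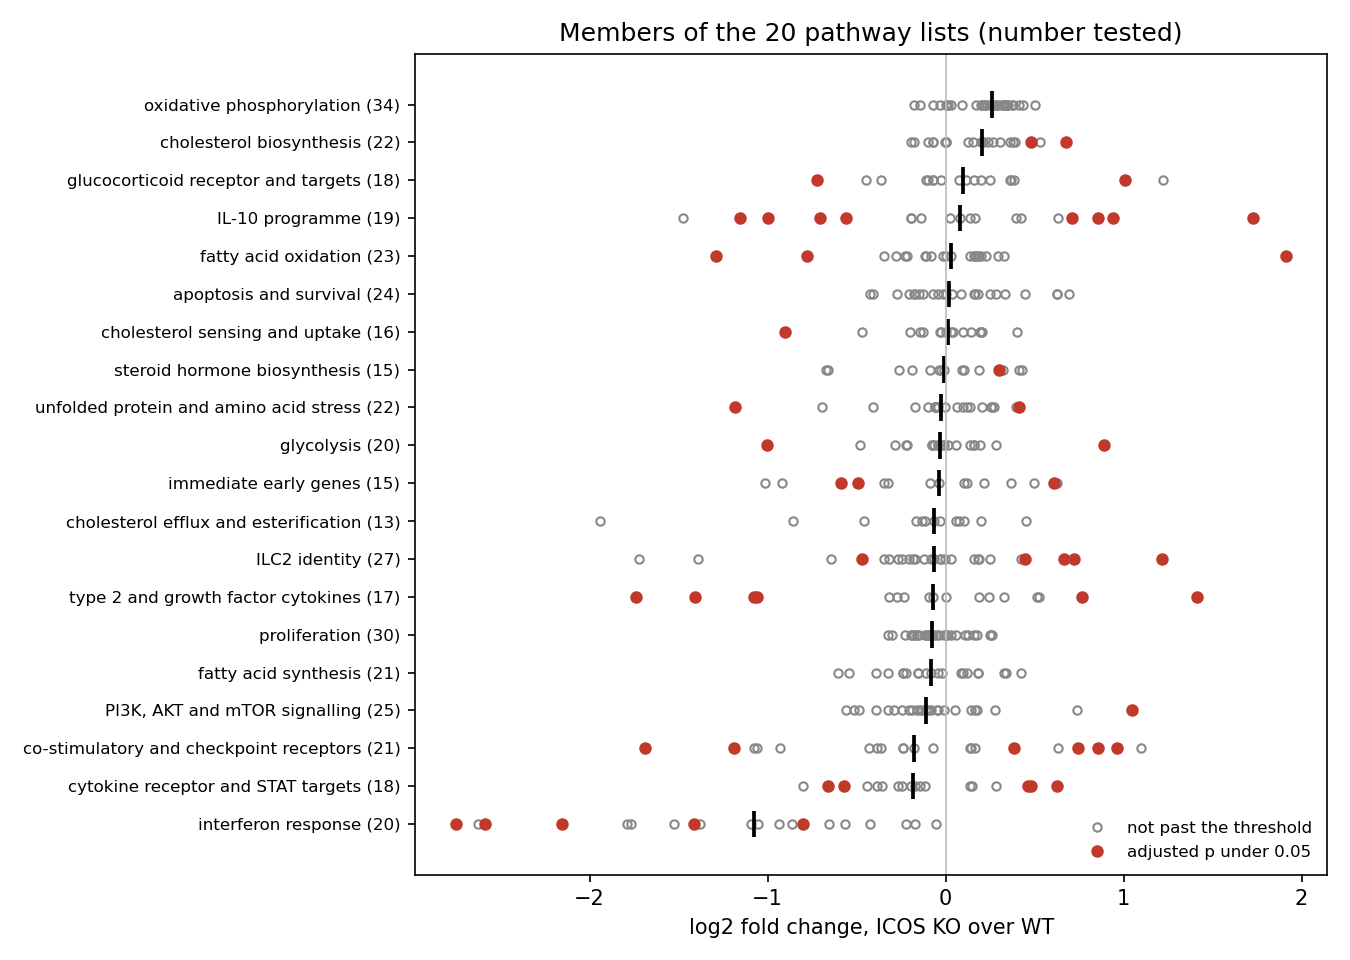
Log2 fold changes (ICOS KO over WT) of the tested members of the 20 pathway lists, with filled red circles for genes at an adjusted p under 0.05, open circles for the others and a black line at each list's median. The interferon response list has the lowest median, -1.07, and the oxidative phosphorylation list the highest, 0.26.

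All 20 tested interferon response genes had negative fold changes, with a median log2 fold change of -1.07, and camera placed the list lower in ICOS KO (adjusted p = 1.42e-08; adjusted p = 0.96 with an estimated correlation). In it 5 genes fell, namely Usp18, Rtp4, Ddx58, Ifit1 and Irf7, or 14 when adjusted over the list alone, and Irf7, outside the rule for named genes, was chosen after its values were seen. Usp18, which removes ISG15 from proteins, fell from 16.1 ± 6.31 to 3.59 ± 1.70 CPM (SD, n = 3 each; edgeR adjusted p = 0.00934), and Ddx58, the RNA sensor RIG-I, from 46.3 ± 3.74 to 26.5 ± 4.92 CPM. Ifit1 fell from 4.43 ± 1.74 to 0.642 ± 0.405 CPM and Rtp4 from 5.16 ± 2.80 to 0.846 ± 0.158 CPM. Cmpk2, another interferon-induced gene and one of the 10 largest falls, went from 5.15 ± 3.19 to 0.380 ± 0.411 CPM. Of 12 macrophage and dendritic cell markers 5 fell as well, and of 7 mast cell and basophil markers 6. The calls of Ddx58, Ifit1 and Rtp4 were lost without ICOS KO replicate 3, those of Ddx58 and Ifit1 also without WT replicate 2 or 3, and that of Cmpk2 without WT replicate 1 or 3 (adjusted p up to 0.0862). The adjusted p of Cmpk2 was 0.0576 with voom, and its log2 fold change of -3.73 was -3.12 without WT replicate 3 and -4.85 without ICOS KO replicate 3.

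Of 34 oxidative phosphorylation genes, 30 had positive fold changes, with a median log2 fold change of 0.26, and camera placed the list higher in ICOS KO (adjusted p = 0.00066; adjusted p = 0.96 with an estimated correlation, and 0.375 with the length and GC trend removed). None of them was called by edgeR, over all genes or adjusted over the list alone, while 14 had an unadjusted p under 0.05, DESeq2 called 2, voom 0 and voom with sample quality weights 2. The 13 mitochondrially encoded transcripts were all positive, with a median of 0.82. None of these was called by edgeR over all genes or by voom, 10 were when adjusted over the list alone or at an unadjusted p under 0.05, DESeq2 called 3 and weighted voom 7. These transcripts took 0.263%, 0.294% and 0.422% of counts in WT and 0.329%, 0.616% and 0.492% in ICOS KO. Malat1, a nuclear RNA, stood at 610, 664 and 996 CPM in WT and at 811, 1687 and 1413 CPM in ICOS KO. The transcript listed as CT010467.1 stood at 2808, 3528 and 3312 CPM in WT and at 3478, 10680 and 4651 CPM in ICOS KO, where replicate 2 was highest for all of these measures. Of 23 fatty acid oxidation genes, Acads rose, which, like the other differences, cannot be told apart from a strain difference. Cd36, a fatty acid importer, fell from 50.9 ± 2.47 to 20.8 ± 3.15 CPM (SD, n = 3 each, edgeR adjusted p = 0.000563). Lpl, lipoprotein lipase, fell from 62.6 ± 3.60 to 36.5 ± 2.34 CPM. When adjusted over the list alone, 1 rose and 2 fell as well. Of 20 glycolysis genes, Hk2, hexokinase 2, fell from 76.5 ± 12.4 to 38.2 ± 7.61 CPM and Aldoc, aldolase C, rose from 13.72 ± 1.744 to 25.44 ± 5.643 CPM, or 1 rose and 2 fell when adjusted over the list alone. Both calls were lost without WT replicate 2, and that of Aldoc also without WT replicate 1 or ICOS KO replicate 3 (adjusted p up to 0.052 and 0.126). No gene was called by edgeR among 21 of fatty acid synthesis, 30 of proliferation and 24 of apoptosis and survival, over all genes or adjusted over the list alone, nor by voom. At an unadjusted p under 0.05 there were 4, 4 and 8, while DESeq2 called 1, 0 and 1 and weighted voom 0, 1 and 2.

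Of 22 genes of the unfolded protein and amino acid stress list, the stress transcription factor Atf3 fell from 16.1 ± 2.10 to 7.06 ± 0.652 CPM (SD, n = 3 each; edgeR adjusted p = 0.00609) and Creld2, an endoplasmic reticulum protein, rose from 297 ± 6.93 to 395 ± 19.2 CPM. Of 15 immediate early genes, Zfp36, an mRNA-destabilising protein, rose from 49.3 ± 2.84 to 75.1 ± 3.33 CPM, while Myc fell from 90.9 ± 7.71 to 64.7 ± 5.17 CPM and Egr1 from 67.3 ± 12.4 to 44.7 ± 3.04 CPM. When adjusted over the list alone, 1 rose and 1 fell in the first list and 4 rose and 5 fell in the second. The calls of Creld2, Zfp36, Myc and Egr1 were lost without WT replicate 1. Those of Creld2, Myc and Egr1 were also lost without WT replicate 2 or ICOS KO replicate 3, those of Creld2 and Myc without WT replicate 3, those of Myc and Egr1 without ICOS KO replicate 2 and that of Egr1 without ICOS KO replicate 1 (adjusted p up to 0.237). The adjusted p of Creld2 was 0.054 with library totals alone, and that of Egr1 0.0555 with voom, 0.0565 with no filter on low counts and 0.0893 with the length and GC trend removed. None of 12 heat shock genes was called by edgeR or voom, 1 fell when adjusted over the list alone, 1 had an unadjusted p under 0.05, and DESeq2 and weighted voom called 1 each. Camera placed no pathway list past the threshold other than cholesterol biosynthesis, interferon response and oxidative phosphorylation (adjusted p from 0.831 to 0.928 in the other 17). Fry's directional test and camera with an estimated correlation placed none. For cholesterol, interferon and oxidative phosphorylation, the unadjusted p of the latter was 0.259, 0.0865 and 0.233. Their estimated correlations were 0.241, 0.414 and 0.296, against the preset 0.01. Fry's mixed test, for change in either direction and not among the alternatives, gave adjusted p of 0.00166, 0.00658 and 0.11 for the same lists. Most other lists also passed it, such as steroid hormone biosynthesis (0.0106), ILC2 identity (0.000101) and immediate early genes (3.39e-05). Cholesterol efflux (0.289), proliferation (0.11) and fatty acid synthesis (0.0539) did not. It thus does not set the cholesterol and interferon lists apart. Camera's direction and the median differed in sign for steroid hormone biosynthesis, ILC2 identity (median -0.07, up) and the unfolded protein list (median -0.02, up).

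Markers of other cell types that a lung sort could hold moved apart. Of 7 tested mast cell and basophil markers 6 fell, with a median log2 fold change of -2.66, or 7 when adjusted over the list alone. Cpa3, mast cell carboxypeptidase, fell from 27.6 ± 3.48 to 1.47 ± 1.04 CPM (SD, n = 3 each), and the tryptase gene Tpsab1 from 249 ± 27.0 to 29.7 ± 7.55 CPM (edgeR adjusted p = 4.24e-06). Its near copy Tpsb2 fell from 27.1 ± 3.69 to 4.28 ± 0.303 CPM, and reads of this pair may have been split between them. The chymase Cma1 fell from 26.5 ± 3.89 to 5.83 ± 1.87 CPM, and the basophil protease Mcpt8 from 9.32 ± 2.58 to 1.70 ± 0.705 CPM. The sixth called marker, Fcer1a, stood at 1.73 ± 0.0847 and 0.0752 ± 0.130 CPM, the latter from 3 reads. Ctsg, cathepsin G, which is on none of these lists, fell from 5.17 ± 0.332 to 0.512 ± 0.315 CPM. Of 12 macrophage and dendritic cell markers 5 fell, or 8 when adjusted over the list alone. Cd74, the invariant chain of MHC class II, fell from 105 ± 9.33 to 55.0 ± 5.88 CPM, and Csf1r from 11.3 ± 2.19 to 3.86 ± 1.26 CPM. The other 3, H2-Aa, H2-Ab1 and H2-Eb1, are MHC class II genes that ILC2s can also express. The calls of Fcer1a (without any of the WT replicates or ICOS KO replicate 3), Csf1r (without WT replicate 1 or ICOS KO replicate 3), H2-Aa (without WT replicate 1 or 3 or ICOS KO replicate 3), H2-Ab1 (without WT replicate 1 or 2 or ICOS KO replicate 2) and H2-Eb1 (without WT replicate 1) were lost, with adjusted p up to 0.138. The log2 fold change of Cpa3, -4.22, was -4.83 without ICOS KO replicate 3. That of Fcer1a, -4.45, was -3.85 without ICOS KO replicate 1. Without ICOS KO replicate 2, it was fitted at -7.83 over an ICOS KO group with no read, so only its direction holds.

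**Figure D3:**
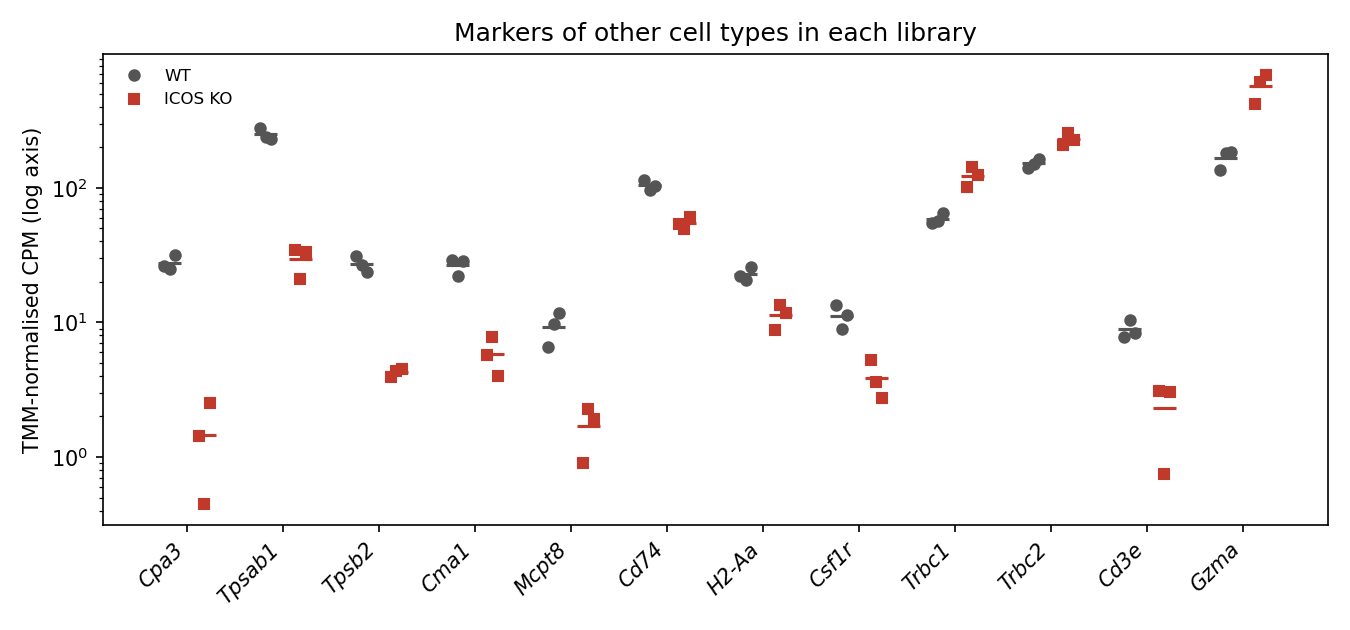
TMM-normalised CPM (log axis) of 12 marker genes of other cell types in the 3 WT libraries (grey circles) and the 3 ICOS KO libraries (red squares), with the group mean as a line. Tpsab1 sat near 249 CPM in WT and 29.7 CPM in ICOS KO, and Gzma near 168 and 574 CPM.

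Of 9 T cell markers 2 rose and 1 fell (3 and 1 when adjusted over the list alone). The T cell receptor constant genes Trbc1 (59.0 ± 5.39 to 123 ± 20.9 CPM; edgeR adjusted p = 0.00126) and Trbc2 (152 ± 12.6 to 231 ± 23.7 CPM; edgeR adjusted p = 0.0104) rose, and Cd3e fell from 8.87 ± 1.42 to 2.30 ± 1.34 CPM; the list's median log2 fold change was 0.26 and its mean -0.05, and reads of Trbc1 and Trbc2 may be shared. Of 7 B cell markers Igkc (807 ± 216 to 1276 ± 140 CPM) and Cd79b (19.1 ± 1.76 to 31.9 ± 7.29 CPM) rose, and 3 rose when adjusted over the list alone. Of 4 tested NK cell and ILC1 markers the granzyme gene Gzma rose from 168 ± 26.9 to 574 ± 135 CPM (edgeR adjusted p = 0.000219), while Ncr1 (1.42 ± 0.215 and 0.0247 ± 0.0429 CPM, the latter from 1 read) and Tbx21 (2.07 ± 0.874 and 0.179 ± 0.196 CPM) fell. It was 2 and 2 when adjusted over the list alone. Of 5 ILC3 markers Lta, which encodes lymphotoxin alpha, fell from 194 ± 7.14 to 54.4 ± 5.01 CPM (edgeR adjusted p = 4.24e-06) and Nrp1 from 19.3 ± 2.02 to 9.48 ± 0.247 CPM, or 2 rose and 3 fell when adjusted over the list alone. Epcam rose from 46.4 ± 1.15 to 76.1 ± 5.15 CPM, while the other 9 of 10 lung epithelium markers had negative fold changes that were not called. That list's median was -0.47, and Sftpc, a surfactant protein gene, stood at 33.0 ± 12.3 and 8.11 ± 7.73 CPM (edgeR adjusted p = 0.141). Of 2 erythroid markers Hba-a1 rose (2.76 ± 1.29 to 9.10 ± 4.05 CPM), and both lists had 1 rise also when adjusted over the list alone. The lists of eosinophils (3 tested), neutrophils (6, with a median log2 fold change of 0.06 and a mean of -0.06), endothelium (2) and fibroblasts (2) had no gene called by edgeR over all genes or by voom. At an unadjusted p under 0.05 there were 1, 2, 1 and 0, and DESeq2 and weighted voom each called 0, 1, 1 and 0. Adjusted over the list alone, 1 eosinophil, 1 endothelium and 1 neutrophil gene were higher, and 1 neutrophil gene lower. The calls of Trbc2, Cd3e, Igkc, Cd79b, Tbx21 and Hba-a1 were each lost without WT replicate 1 or 2 or ICOS KO replicate 3, those of Cd3e, Cd79b, Tbx21 and Hba-a1 also without WT replicate 3 and those of Igkc, Tbx21 and Hba-a1 also without ICOS KO replicate 2 (adjusted p up to 0.201). The log2 fold change of Ncr1, -5.50, was fitted at -7.55 without ICOS KO replicate 3. No ICOS KO read was left in that fit, so only its direction holds. For Tbx21, the log2 fold change of -3.43 was -4.66 without ICOS KO replicate 1. With the length and GC trend removed the adjusted p was 0.056 for Trbc2, 0.0591 for Cd79b, 0.0852 for Igkc and 0.0564 for Hba-a1. With no filter on low counts the calls of Cd79b, Igkc, Tbx21 and Hba-a1 were lost (adjusted p up to 0.0596), with library totals alone those of Cd79b, Igkc and Hba-a1 (up to 0.0662) and with voom those of Cd79b and Hba-a1 (up to 0.0574).

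Among 40 tested genes flanking Icos on chromosome 1, 2 fell and none rose in edgeR, or 1 rose and 2 fell when adjusted over the list alone, while DESeq2 called 3, voom 2 and weighted voom 3, and the median log2 fold change was -0.03. Bmpr2, a BMP receptor, fell from 10.5 ± 1.95 to 3.21 ± 0.412 CPM (SD, n = 3 each; edgeR adjusted p = 0.00355), and Klf7, a Krüppel-like transcription factor, from 53.7 ± 2.25 to 35.2 ± 1.801 CPM. The call of Klf7 was lost without WT replicate 1 or 2 or ICOS KO replicate 3 (adjusted p up to 0.0852) and with the length and GC trend removed (0.0604). Xist, the RNA of the inactive X chromosome, stood at 72.0 ± 10.4 and 77.2 ± 9.13 CPM (edgeR adjusted p = 0.705); of the 2 tested genes of the sex chromosome list, edgeR, DESeq2 and voom with or without quality weights called 0, and 1 was higher when adjusted over the list alone and at an unadjusted p under 0.05.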

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

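The length and GC correction and the fit without marker and antigen receptor genes were chosen after the data were seen. Icos (log2 fold change -1.634 to -1.479) and Il10 (1.575 to 1.811) kept direction and call under all 18 alternatives, with adjusted p up to 0.000388 for each, and the steroid hormone list was past the threshold under none of 20 (adjusted p 0.27 to 0.96). Over 172 genes, 2725 of 3020 values under the alternatives kept direction and side of the threshold, 192 lost the call, 78 gained one and 25 changed sign. Of the 95 called genes among these 172, 49 stayed past the threshold in all 6 fits without 1 library. These 95 were mostly picked by p or fold and do not stand for all calls. Of all 451 calls, from 181 (without WT replicate 1) to 427 (without ICOS KO replicate 1) were kept in a single such fit. None of the genes or lists that changed sign was called by the main test (smallest adjusted p of such a gene 0.346). Marker, antigen receptor, mitochondrial and low-count genes have no value under the alternatives that leave them out. Depth limits the lowest genes, since a count of 3 reads is up to 0.225 CPM in a library.

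The count of called genes, 451 (176 higher, 275 lower), became 909 (402, 507) with DESeq2, 906 (399, 507) with weighted voom and 201 (61, 140) with a 2-fold minimum, and with length and GC removed 353 genes were higher. Leaving out 1 library gave 193 to 1090 calls, 69 to 491 higher and 123 to 599 lower; fits with fewer libraries have fewer degrees of freedom, and the rise without ICOS KO replicate 1 has no tested cause. The replicate number as a block gave 784 calls, 374 higher. Libraries of the same number correlated by 0.087, 0.078 and 0.064 in their deviations from the group means, and those of unlike numbers by -0.082 to 0.007. Each correlated best with its own number, a hint from the data and not the design. A shared day or batch thus stays open, and the main fit did not model it. The cholesterol biosynthesis list had an adjusted p of 0.96 with an estimated correlation, 0.27 with fry and 0.000212 to 0.263 without 1 library. Beyond the construction of these settings, the cause was not tested.

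Sign changes in log2 fold change were as follows. With the length and GC trend removed they were 0.008 for Mbtps1, 0.077 for Sqle, 0.066 for Hspa8, 0.075 for Pdgfrb and 0.078 for Bzw1. Bzw1 was 0.001 with RLE, 0.002 with the 5 CPM filter, 0.011 with weighted voom and 0.019 with upper-quartile scaling, and Hsp90ab1 was -0.052 with total counts. Without 1 library the ranges were -0.24 to 0.023 for Sqle, -0.088 to 0.018 for Hspa8, -0.004 to 0.037 for Hsp90ab1, -0.328 to 0.197 for S100a8, -0.23 to 0.122 for S100a9, -2.242 to 0.036 for Scgb1a1, -0.891 to 0.205 for Pdgfrb, and -0.038 to 0.044 for Bzw1.

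Lists whose direction turned had these adjusted p. With length and GC removed they were 0.871 for cholesterol efflux and for STAT targets, 0.626 for PI3K and for glycolysis, 0.779 for proliferation and 0.731 for fatty acid synthesis. Cholesterol sensing was at 0.989 with total counts, 0.874 with weighted voom, 0.789 without a filter and 0.81 with fry. Glycolysis was at 0.992 with upper quartiles, 0.995 with voom, 0.972 with weighted voom and 0.999 with the 5 CPM filter. ILC2 identity was at 0.943 with the block, and immediate early genes at 0.918 with fry. Without 1 library the ranges were 0.73 to 0.983 for cholesterol sensing, 0.853 to 0.97 for ILC2 identity, 0.698 to 0.936 for proliferation, 0.73 to 0.977 for glycolysis and for fatty acid synthesis, 0.492 to 0.97 for the unfolded protein list and 0.73 to 0.965 for immediate early genes.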

Other observations

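The tests of adjacent genes, of Il10, of mast cell markers and of transcript length were chosen only after the result was seen. Called genes often lay side by side: 44 pairs of adjacent tested genes were called in the same direction, against a mean of 7.73 and a maximum of 22 in 10000 permutations of gene order (p = 1e-04, the smallest these permutations can give), overlapping genes and paralogs included. On chromosome 17, Btbd9 (30215524 to 30576488) fell from 102 ± 10.3 to 27.6 ± 2.93 CPM (SD, n = 3 each), Glo1, the methylglyoxal-detoxifying glyoxalase 1 (30584936 to 30626871), from 611 ± 9.11 to 241 ± 13.8 CPM, and Dnah8 (30624354 to 30877365) from 85.6 ± 11.0 to 41.8 ± 2.50 CPM. 1700097N02Rik, which overlaps both Glo1 and Dnah8, fell from 55.7 ± 7.25 to 16.8 ± 3.23 CPM. All 4, chosen after their values were seen, were called by edgeR (adjusted p up to 0.000876), and this segment is known to differ in copy number between inbred mouse strains. Eosinophil granule genes, too uneven to pass the filter, were seen in 2 WT libraries. Prg2 stood at 8.39 and 24.7 CPM in WT replicates 1 and 2 and at up to 0.520 CPM in the other 4 libraries. Epx stood at 7.24 and 17.4 CPM and at 0 in the others. Elane, of the neutrophil list and also below the filter, stood at 3.42 CPM in WT replicate 2 and at up to 0.0656 CPM elsewhere.

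Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave 451 called genes or more, and the highest other split gave 0 with edgeR (up to 2075 genes at an unadjusted p under 0.05, with WT replicates 1 and 2 beside ICOS KO replicate 1, against 2718 in the real one). For pathway lists past the threshold in camera, again only 1 split reached the real count of 3, and the highest other gave 2. With 10 splits no share under 0.05 can be reached.

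For the rise of Il10 by 108 CPM, more RNA from T cells stays open, because the T cell markers did not move alike. Of the 9 under 10 CPM in WT, none gained more than 0.251 CPM (Cd6). That cut was set after the values were seen, and some of these genes were too low to be tested. Above the cut, Trbc1 and Trbc2 rose, and Cd3g stood at 48.2 and 63.3 CPM (edgeR adjusted p = 0.214). More RNA from B cells or plasma cells stays open, because the immunoglobulin genes together gained 1230 CPM, with 9 of 80 tested called higher and 3 lower, while the 5 B cell markers under 10 CPM gained at most 0.227 CPM (Cd79a) and a sort for ILC2s would remove most such cells. Scaling of the libraries is argued against by a log2 fold change of at least 1.663 under RLE, upper-quartile and total-count scaling (adjusted p up to 1.29e-05). Strain DNA, around Il10 or elsewhere, cannot be told apart from the loss of Icos. The ICOS KO strain name includes 129S4 but does not give how much of the DNA is of that origin, and all ICOS KO libraries share this name. Of 21 tested genes within 1 Mb of Il10, 2 were called, Fcmr (8.78 to 18.3 CPM) and Il24 (21.8 to 48.9 CPM). Both were higher (Fisher's exact p = 0.15 against the rest of the genome). The call of Il24 stayed in all 6 fits without 1 library, while that of Fcmr stayed in only 1 of them, that without ICOS KO replicate 1 (adjusted p up to 0.12). A direct effect of Icos loss on Il10 in ILC2s remains a hypothesis, untested here.

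The fall of mast cell and basophil markers was weighed against a single library, a change in all other cells and a change in those cells alone. Markers brought by 1 library are argued against because at least 5 of the 6 called markers stayed past the threshold in each fit without 1 library. A fall of every other cell type as large as that of these markers is argued against. The 62 tested markers of other types had a median log2 fold change of -0.20 (SD 1.32), with 7 higher and 10 lower. That lay above -2.66, the median of the mast cell and basophil markers, by more than the SD. The 35 of them under 10 CPM in WT also did (-0.19, SD 1.40). Smaller falls stay open, as the 62 include genes abundant in WT, such as Igkc (807 CPM) and Lta (194 CPM). Negative fold changes were seen in 11 of 12 macrophage and dendritic cell markers and 9 of 10 of lung epithelium. They were seen in 4 of 9 T cell and 3 of 7 B cell markers. In the NK cell and ILC1 list it was 2 of 4 and in the ILC3 list 3 of 5, with medians of -1.27 and -1.03. The medians of the eosinophil, neutrophil, endothelium, fibroblast and erythroid lists were positive. Less mast cell or basophil RNA in ICOS KO stays open: in a second marker list of 20 genes, 5 of 9 tested were lower at an unadjusted p under 0.05 and 0 higher (2 at an edgeR adjusted p under 0.05, Gata2 and Ctsg), but it was 3 of 7 without Ctsg, already seen to fall, and Tph1, and 3 of 5 without Ctsg and the 3 that the ILC2 identity list also holds, Tph1, Kit (20.3 and 20.2 CPM) and Hpgds. Lower expression of these genes within ILC2s was not tested, and a sort for ILC2s would remove most mast cells.

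The rises of the oxidative phosphorylation and cholesterol biosynthesis lists were weighed against a trend with transcript length and GC content, since log2 fold changes across genes, which are not independent, correlated with transcript length (Spearman rho = -0.369) and hardly with GC (0.002). For oxidative phosphorylation, whose transcripts had a median length of 1553 against 3008 bases over all tested genes, removing the trend moved the median log2 fold change from 0.261 (SD 0.170 over members) to 0.069 (SD 0.155) and the camera adjusted p to 0.375, so the trend may account for that rise; the call ended because the shift shrank, not because the spread grew. For cholesterol biosynthesis the median went from 0.203 to 0.238 and the adjusted p to 0.000552, which argues against the trend as the cause. Whether the trend itself is technical, such as a difference in RNA integrity, or belongs to the genotype stays open, as the sources used here give no measure of RNA integrity. The trend took 12.2%, 9.23% and 2.45% of the variance, across genes, of the deviations of WT replicates 1, 2 and 3 from the mean of all libraries, and 0.646%, 7.41% and 5.76% in ICOS KO, shares that carry no direction. The loss of both calls with an estimated correlation (adjusted p = 0.96) stays open too.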
